A study of Caenorhabditis elegans with 2 samples.

How the data were processed

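The data are peak lists from ChIP-seq of eGFP-FOS-1 in whole L3 larvae, with 2 biological replicates that the labels number 1 and 2 and no further group. The size range was 150 to 350 bp, per the labels. The authors deposited, for the ce11 and ce10 builds, a relaxed list of peaks and background for each replicate, a relaxed list called on the alignments of both replicates together with a control, and a list of IDR-thresholded peaks derived from the pooled and the replicate lists. The caller, its version, the IDR threshold, the aligner and the read depth are not given in the sources used here, so no counting error of the signals can be stated. Control reads and signal tracks were not analysed here.

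The signal of a region is the authors' own value from the deposited list, on a scale whose normalization is not stated, and it was used to rank and describe regions within one list, to correlate the signals of matched regions between the replicates and to compare ranked signals between the builds. The -log10 q value of a region is likewise the authors' deposited value. It reached its maximum of 2.80 in 318 of the 561 IDR peaks, so it could not rank them and signal was used instead. The pooled relaxed list goes down to a q of 96.0%, and its regions away from the IDR peaks served as background, not as binding sites. This background includes regions ranked just below the IDR peaks, some of which are looked at again in the additional observations, so it may hold bound regions. Both replicate lists hold exactly 30000 regions, which looks like a cap, and no source used here states one. Nearly all regions have one width, 340 bp in the IDR list (551 of 561, the narrowest 87 bp), so widths carry little information and summits were used throughout.

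All coordinates are ce11, 1-based. Sequence and annotation came from the WBcel235 assembly, which is the same assembly as ce11, with Ensembl release 115 gene models. All list coordinates lay within the reference chromosome lengths. Lists on ce10 were used for counts, widths and ranked signals only.

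Background regions were the 17150 pooled regions with a summit over 500 bp from every IDR summit. Replicate agreement was the share of IDR peaks with a summit of each replicate's own list within 100 bp, against 100 circular shifts along each chromosome. Locations, motifs, 7-base sequences and gene lists were tested with Fisher's exact test, two-sided, and Benjamini-Hochberg adjustment within each family (7 classes, 10 motifs, 8192 sequences, 21 lists), with a threshold of 0.05. Chromosome shares were tested with exact binomial tests, and the signal of peaks with and without an AP-1 site with a permutation test of the difference in medians (100000 resamples). Motifs and sequences were sought on both strands within 75 bp of the summit, and a site counted only where all of its bases lay in that window. By that rule the *nhr-50* peak, with an AP-1 site centred at -73 bp from the summit, counted as without a site. Shares carry 95% Wilson intervals, which treat peaks as independent. No test across samples was possible with 1 group of 2 replicates.

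The genes named are the 20 with the highest IDR signal (1 gene per peak, the nearest 5' end with the summit from 1500 bp upstream to 500 bp downstream, symbols of letters and numbers), the 2 members of each list with the highest signal, and *fos-1*, *jun-1*, *egl-43*, *zmp-1*, *cdh-3* and *him-4* whatever their value. This rule, the lists, the motifs, the tests and most of the other settings tried were fixed before the data were examined. Further genes are named as chosen after their values were seen, or as members of a list with 5 or fewer genes with a peak. The symbols atf-5, numr-2, hpo-24, hsp-16.11 and hsp-16.49 had no match in the annotation and were left out of their lists. The plan to look up the microRNA genes let-7 and lin-4 was dropped because no gene of those symbols was matched, and they were not analysed here.

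Other settings tried were the 280 strongest peaks, each replicate left out in turn (replaced by the 561 strongest regions of the other replicate alone), other matching distances, windows and backgrounds, and background regions matched on GC content in bins of 2%. Matching to 5 regions per peak ran short in the GC-richest bins (2596 of 2805 found, mean GC 43.6% against 44.7%), so 1 region per peak (561 found, mean 44.7%) was added after seeing the data. Also added then were gene lists with each peak given only to its nearest gene, against genes matched on GC content and without peaks near small RNA genes, and promoter shares against GC-matched regions.

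The tests were first tested on simulated data. In shuffled windows 0 of 8192 sequences were called without a planted site, and a sequence planted in some of the windows was recovered, together with 5 others. Both sets of windows were drawn at random from the same regions, so they shared their base content, unlike the real peaks and background. That simulation therefore does not cover sequences called because of GC content. Over 100 simulations with random genes as hits, 2 of 2100 list tests were called. With many extra hits planted in 3 lists, 300 of 300 planted lists were recovered, together with 10 calls of other lists. Weaker enrichment was not simulated. Hits were drawn gene by gene, while a real peak can mark neighbouring genes. The rate of false calls may therefore not hold for lists of clustered genes. For a site whose frequency depended on GC content alone, all background regions gave a call in 100 of 100 simulations (median odds ratio 3.24), 5 matched regions per peak in 15 (1.15) and 1 matched region per peak in 1 (1.03). Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.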

Results

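FOS-1 is the Fos-family basic leucine zipper (bZIP) transcription factor of the nematode *Caenorhabditis elegans*. Its binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) of a green fluorescent protein fusion, eGFP-FOS-1, in whole third-stage (L3) larvae of strain OP304, which carries the fusion as an integrated transgene. The series holds 1 group with 2 biological replicates, so the samples allow a comparison of the replicates with each other, of peaks with weaker regions and of genes with genes, but no comparison between conditions. Each replicate has a relaxed list of 30000 regions in the ce11 build, the reads of both together gave a pooled relaxed list of 17769 regions, and 561 of these form the final list selected by irreproducible discovery rate (IDR), a measure of how consistently replicates rank a region. These 561 IDR peaks were the 561 pooled regions with the highest signal, from 36.3 to 297.8, and their q values were at most 0.715%. Read depth is not given in the sources used here. Peaks and genes within one pooled list are not independent replicates, so the p-values below describe this list and not the spread between animals.

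The strongest peak of the whole list lay at *cebp-1*, a bZIP factor of the C/EBP family, and the fourth strongest at the promoter of *jun-1*, the worm's c-Jun homolog. Both carried the AP-1 site TGASTCA, where S is C or G. The *cebp-1* peak, at chromosome X 1454467 to 1454784 with its summit in the promoter at -737 bp from the gene's 5' end (negative is upstream), had a pooled signal of 297.8 and was the strongest region in replicate 1 (signal 164.1) and in replicate 2 (132.8). Its site lay at 1454587 to 1454593, in the sequence CTTGCGATGAGTCACAACGCC. The *jun-1* peak, at chromosome II 9113056 to 9113197, had a pooled signal of 165.3 and ranked 11 in replicate 1 and 5 in replicate 2. A second *jun-1* peak, chosen after its value was seen, lay within the gene at 9126969 to 9127308, at -198 bp from the start of a shorter transcript, with a signal of 125.0, an AP-1 site within 75 bp of the summit and another centred 75 bp away that reaches past that window. *vhp-1*, which encodes a phosphatase that acts on stress-activated MAP kinases, was named by the rule through a weak upstream peak (signal 37.03, matched in replicate 2 but not in replicate 1). The strongest peaks at this gene, chosen after their values were seen, inside it. An intronic peak at chromosome II 5336854 to 5337193 had a signal of 145.4, rank 9 and an AP-1 site, and another intronic one at 5332765 to 5333104 had a signal of 104.7 and no site. Another peak at 5337406 to 5337745, in the promoter of a shorter transcript, had a signal of 58.3 and an AP-1 site.

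**Figure D1:**
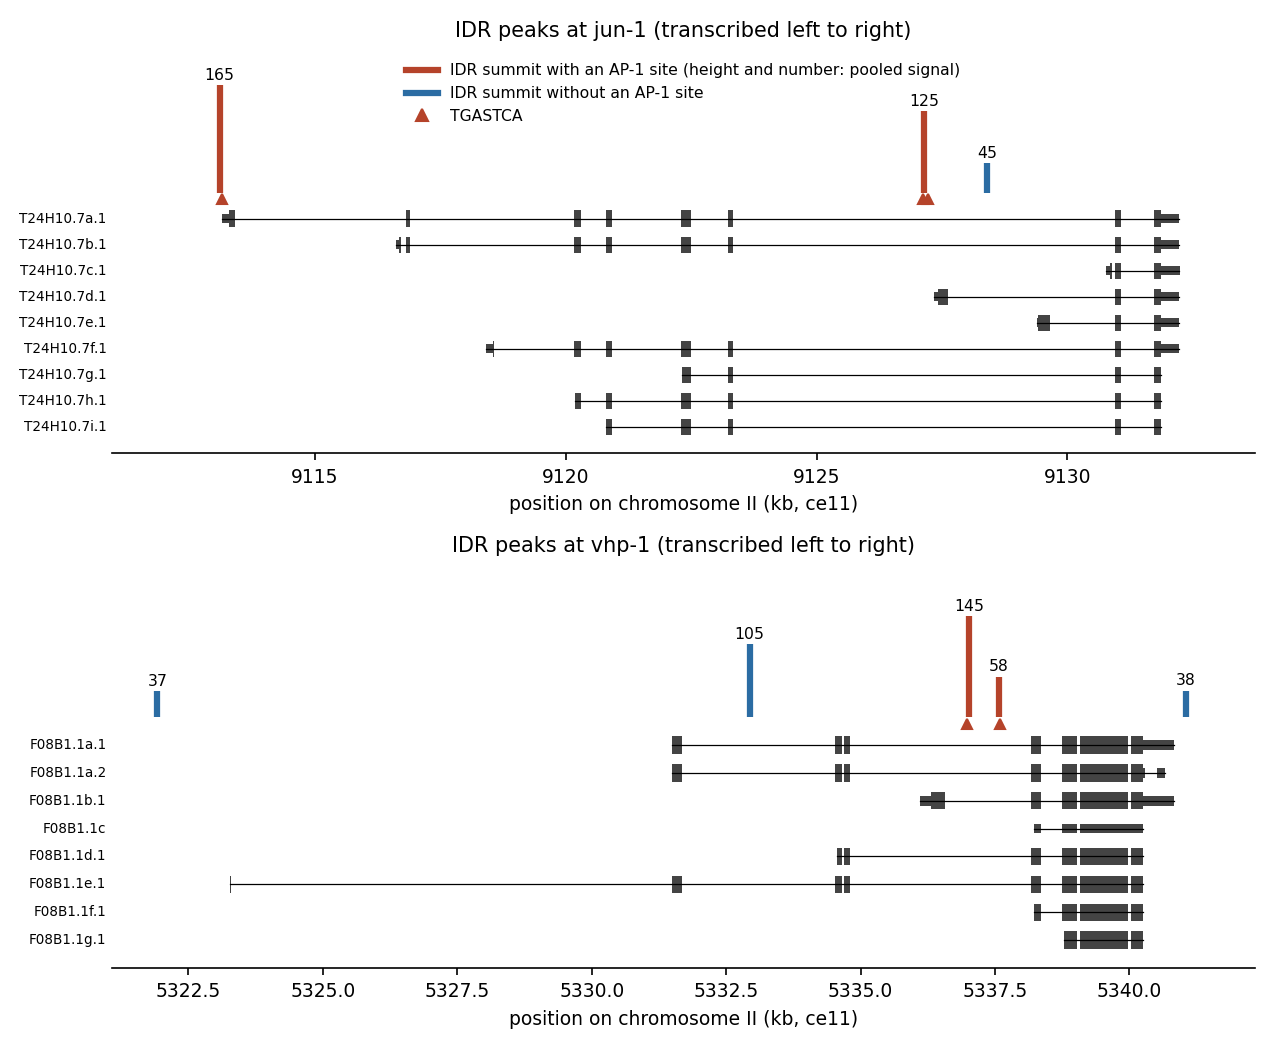
IDR peaks along *jun-1* and *vhp-1* (position in kb on chromosome II, ce11), with annotated transcripts below as boxes for exons, taller where coding, and bars above for summits with height and number giving the pooled signal. Red bars are summits with an AP-1 site within 75 bp and triangles mark the sites: 2 of the 3 peaks at *jun-1* and 2 of the 5 at *vhp-1* had one.

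Among the other genes of the 20 with the highest signal were *rpl-3*, *rpl-15* and *rpl-35*, which encode proteins of the large ribosomal subunit, with signals of 240.6, 149.0 and 110.6, and *cdc-48.1*, which encodes the AAA ATPase CDC-48, with 197.4. The cytochrome c oxidase subunit genes *cox-5B* and *cox-5A* had signals of 129.1 and 108.1, *iff-2*, the gene of translation factor eIF5A, 108.3, and the histone gene *his-37* 107.2. *puf-9*, which encodes a Pumilio-family RNA-binding protein, had 138.7, *vps-60* 100.7, and *spc-1*, the alpha-spectrin gene, 99.3. None of these 11 peaks had an AP-1 site within 75 bp. *tag-325* (151.7) and *rib-2* (133.4), a heparan sulphate glycosyltransferase gene, did have one. *tasp-1* (159.6), *nspc-17* (156.2), *fbxb-58* (118.2), *tag-340* (117.6) and *serp-1.1* (100.3) completed the 20, all without a site. Each of the 20 peaks ranked 53 or better in both replicates.

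The replicates overlapped in part in their strongest regions. Of the 561 IDR peaks, 511 (91.1%, 95% Wilson interval 88.4 to 93.2%) had a summit within 100 bp in the relaxed lists of both replicates, against a mean of 1.13% after 100 circular shifts of the peaks along their chromosomes. Part of this match was fixed by the processing. The pooled calls used the reads of both replicates, and the IDR peaks were derived from the replicate lists as well. The 91.1% is thus no independent measure of replicate agreement. Between the replicates' own lists, 58.0% of the 50 strongest regions of replicate 1 had a counterpart among the 50 strongest of replicate 2, and this share was 40.1% (36.1 to 44.2%) for the 561 strongest. Across the 511 matched peaks, Spearman's rho of the signals was 0.22 (95% interval 0.13 to 0.30) and Pearson's r of their log2 values 0.35. This is a correlation across peaks, not across samples, and the choice of these peaks on the signal of both replicates together can lower it, so it does not measure how alike the replicates rank regions in general. Only 231 of the IDR peaks (41.2%) were among the 561 strongest regions of both replicates.

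**Figure D2:**
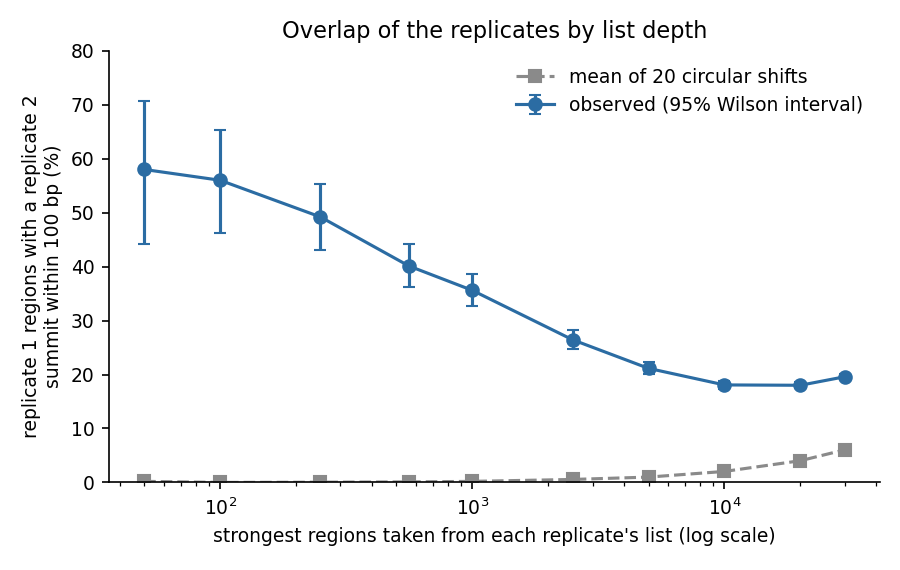
Share of the strongest regions of replicate 1 with a summit of the equally deep replicate 2 list within 100 bp (vertical axis, percent, bars 95% Wilson intervals) against the number of regions taken from each list (log scale), with the mean of 20 circular shifts in grey. The share fell from 58.0% at 50 regions to 18.1% at 10000.

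Sites for AP-1, the dimer that Fos proteins form with Jun proteins, marked a minority of the peaks. TGASTCA occurred within 75 bp of the summit in 56 of 561 IDR peaks (9.98%, 7.77 to 12.7%) and in 369 of 17150 background regions (2.15%), which are regions of the pooled relaxed list over 500 bp from every IDR peak. The odds ratio was 5.04 (Fisher's exact test, two-sided, adjusted p = 7.04e-19 over 10 motifs). The share fell with rank, from 16% of the 100 strongest regions (10.1 to 24.4%) to 7.40% at ranks 251 to 561 (4.98 to 10.9%) and 1.51% at ranks 12001 to 17769. Sites were 6.33 times as dense within 50 bp of the summit as 250 to 500 bp away from it. Background regions rose less toward their summits. Their 50 bp bins on either side of the summit held 0.776 and 0.805 sites per 100 regions, against 0.426 to 0.601 at 250 to 500 bp. Peaks with a site had a median signal of 50.3 against 45.7 without (permutation test, two-sided, p = 0.0314). This last difference was not kept past the threshold in the 280 strongest peaks (permutation p = 0.667), without replicate 2 (permutation p = 0.0811) or with sites sought within 50 bp (permutation p = 0.209).

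**Figure D3:**
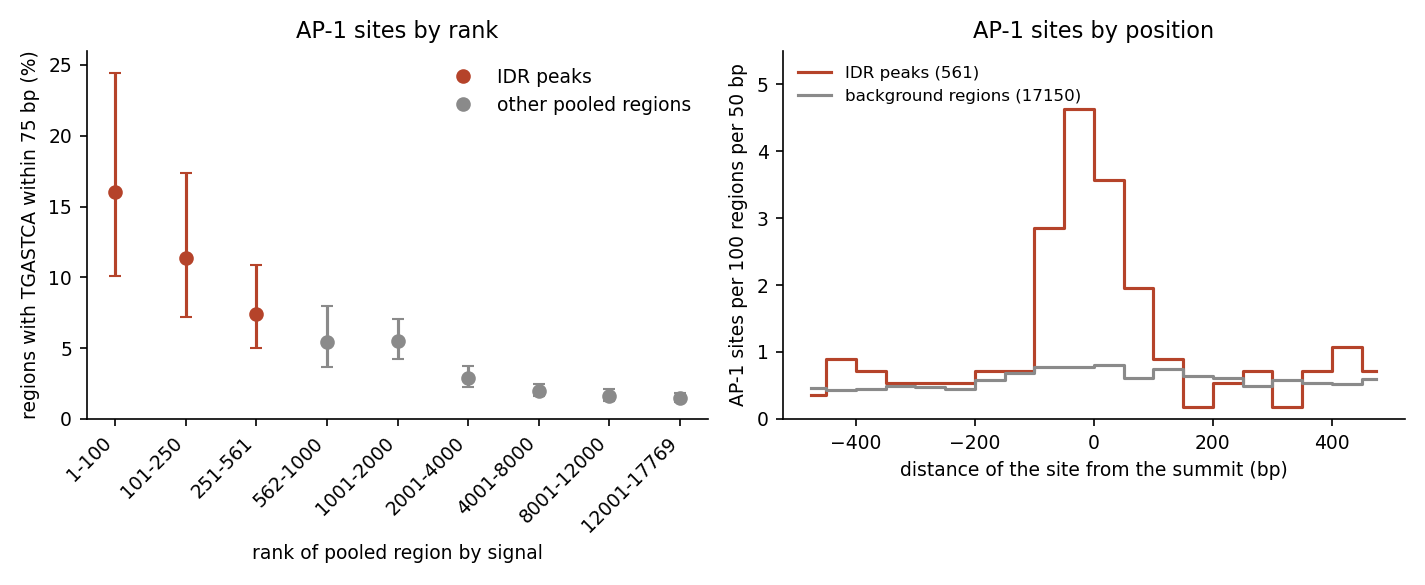
Left, share of pooled regions with TGASTCA within 75 bp of the summit (percent, bars 95% Wilson intervals) by rank of pooled signal, IDR peaks in red; right, AP-1 sites per 100 regions in 50 bp bins by distance from the summit, for 561 IDR peaks (red) and 17150 background regions (grey). The share fell from 16% at ranks 1 to 100 to 1.51% at the lowest ranks, and the sites of IDR peaks gathered around the summit.

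Peak sequences were richer in G and C than background regions, with a mean GC content of 44.7% against 32.98% in the 151 bp around the summit, and the other motifs have to be read beside that difference. A GAGA repeat (GAGAGAGA) was found in 9.80% of IDR peaks and 2.10% of background regions, the SP1-like GC box in 9.09% and 2.74%, the E-box CACGTG in 7.49% and 2.37%, the E-box CAGCTG in 4.63% and 2.59%, and the CRE site TGACGTCA in 1.78% and 0.70%. All 5 were more frequent in IDR peaks by Fisher's exact test, with adjusted p from 7.04e-19 for the repeat to 0.0140 for the CRE site. The heat shock element (7.84% against 10.7%) and the binding element of DAF-16, the FOXO factor of insulin signalling (0.891% against 2.23%), were less frequent (Fisher's exact test, adjusted p = 0.0382 for both). The GATA site (32.1% against 33.7%) and the nuclear receptor site AGGTCA (4.28% against 3.38%) did not pass the threshold (Fisher's exact test, adjusted p = 0.467 and 0.263). With up to 5 GC-matched background regions per peak the AP-1 odds ratio was 4.25, that of the GAGA repeat fell to 1.68 and that of CACGTG to 1.83 (Fisher's exact test, adjusted p = 2.12e-12, 0.00715 and 0.00715). Against 561 background regions, 1 matched to each peak on GC content, a setting chosen after seeing the data, the AP-1 odds ratio was 6.80 (Fisher's exact test, adjusted p = 7.32e-09), and the GAGA repeat (2.07, adjusted p = 0.0141 by the exact test) and CACGTG (2.08, adjusted p = 0.0300 by the exact test) also stayed past the threshold. The GC box, CAGCTG, the heat shock element and the DAF-16 element did not, with adjusted p from 0.723 to 0.911 by the same exact test, and the heat shock element and the GC box changed direction (odds ratios 1.05 and 0.902). The CRE site also missed the threshold there, with 10 peaks against 2 matched regions and a higher odds ratio than against all background regions (5.07 against 2.58, Fisher's exact test, adjusted p = 0.0939). Over the 9 other settings tried, the CRE site lost its call in 7, among them each replicate left out (Fisher's exact test, adjusted p = 0.0919 without replicate 1 and 0.224 without replicate 2). CAGCTG lost its call in 4 and changed direction in 1, and the heat shock element lost its call in 4 and changed direction in 2. The DAF-16 element kept its call in none of the 9 other settings tried, and its odds ratio was 1.17 without replicate 2.

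**Figure D4:**
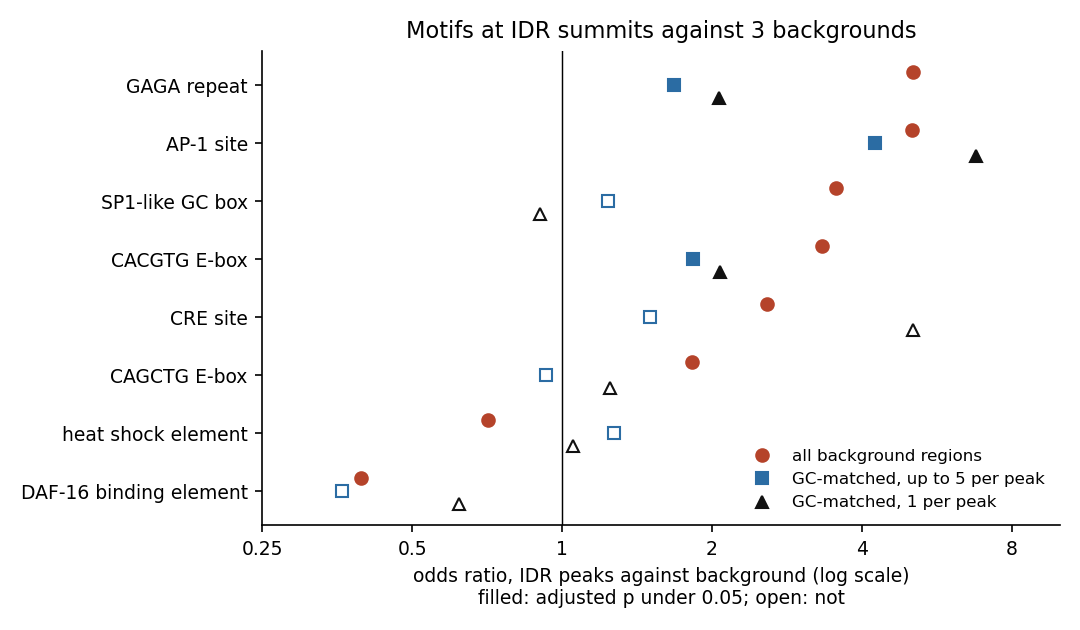
Odds ratios of the 8 motifs that differed between IDR peaks and all background regions (log scale), against all background regions (red circles), up to 5 GC-matched regions per peak (blue squares) and 1 GC-matched region per peak (black triangles), filled where the adjusted p of Fisher's exact test was under 0.05. The AP-1 site lay between 4.25 and 6.80 against all 3 backgrounds, while the GC box fell from 3.55 to 0.902.

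Without any preset motif, the AP-1 site led the 7-base sequences once GC content was matched. Of 8192 sequences counted on both strands, 1370 were more frequent in IDR peaks and 555 less frequent (Fisher's exact test, Benjamini-Hochberg adjusted). The leading higher ones were AGAGACG (14.1% of peaks against 2.47% of background regions) and CTCTCTC (16.04% against 3.55%), the leading lower ones were runs of A and T such as AAAAATT (12.8% against 39.95%), and TGACTCA ranked 38 overall. Against up to 5 GC-matched regions per peak, 45 sequences were higher and 8 lower, and TGACTCA ranked 1 (9.98% against 2.54%, Fisher's exact test, adjusted p = 1.74e-09). With 1 matched region per peak, 3 were higher and 0 lower: TGACTCA (9.98% against 1.60%), CCCTGCG (3.74% against 0.178%) and ATGAGTC (7.31% against 1.78%), the last of which overlaps the AP-1 site. CCCTGCG was found in only 1 matched region. This background was also smaller, with 561 regions against 2596, so fewer sequences could pass. AGAGACG, for example, kept an odds ratio of 2.03 against 2.27 but lost its call (Fisher's exact test, adjusted p = 0.293). The fall from 45 to 3 thus cannot be put down to GC content alone.

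Most summits lay at promoters, here 1000 bp upstream to 200 bp downstream of an annotated transcript start of a protein-coding gene. Promoters held 305 of the 561 summits (54.4%, 50.2 to 58.4%) and 33.4% of the background summits (odds ratio 2.38, Fisher's exact test, adjusted p = 8.95e-23 over 7 classes). Introns held fewer summits than in the background (11.8% against 27.6%, Fisher's exact test, adjusted p = 1.22e-18), as did coding exons (1.78% against 7.31%, adjusted p = 2.00e-08 by the exact test), and other RNA genes held more (4.28% against 1.21%, adjusted p = 6.14e-07 by the exact test). The intergenic share, 24.1% against 26.2%, and the shares of 5' UTRs (0.357% against 0.286%) and 3' UTRs (3.39% against 3.95%) did not pass (Fisher's exact test, adjusted p from 0.366 to 0.677). Genes of small structural RNAs, a class set after the lists were opened, lay within 200 bp of 51 summits (9.09% against 2.67%, Fisher's exact test, adjusted p = 1.92e-12), among them 23 at small nucleolar RNA genes and 11 at small nuclear RNA genes, which both passed, and 14 at tRNA genes, which did not (Fisher's exact test, adjusted p = 0.229).

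The X chromosome held 146 IDR peaks, 26.03% of them on 17.7% of the nuclear genome's length. That is 8.24 peaks per Mb and 1.47 times the share by length (exact binomial test, two-sided, adjusted p = 2.26e-06 over 6 chromosomes). Background regions were also frequent on X, and against their share of 21.8% the odds ratio was 1.26 (Fisher's exact test, adjusted p = 0.0393). Chromosome III held 18.5% of the peaks (1.35 times its share, exact binomial test, adjusted p = 0.00282) and chromosome V 69 of the 561 (0.589 times, exact binomial test, adjusted p = 1.05e-06). Chromosomes I, II and IV, with 74, 88 and 80 peaks, did not differ from their length share past the threshold (exact binomial test, adjusted p from 0.0769 to 0.769).

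An IDR summit lay from 1500 bp upstream to 500 bp downstream of the 5' end of 412 of 19973 protein-coding genes (2.06%), and 263 of the 561 peaks (46.9%) lay in no such window. Of 21 gene lists fixed before the data were examined, 3 held more of these genes than the rest of the genome and 1 held fewer. Ribosomal protein genes had a peak in 16 of 81 cases (19.8%, odds ratio 12.1, Fisher's exact test, adjusted p = 1.67e-10). Heat shock protein genes had one in 5 of 19 (26.3%, odds ratio 17.2, Fisher's exact test, adjusted p = 0.000234). These were *hsp-1* (signal 83.1), the HSC70 gene, *dnj-13* (47.5), *hsp-110* (46.3), the mitochondrial chaperonin gene *hsp-60* (45.8) and the endoplasmic reticulum chaperone gene *hsp-3* (42.7), and none of the matched genes of the stress-inducible hsp-16 family was among them. The peaks counted for *hsp-110* and *hsp-60* lay nearer to the 5' ends of *rpn-3* and *Y22D7AL.10*. With each peak given to its nearest gene only, a setting chosen after seeing the data, heat shock genes had 3 of 19 (15.8%, Fisher's exact test, adjusted p = 0.0139) and ribosomal protein genes 12 of 81 (14.8%, Fisher's exact test, adjusted p = 5.57e-08). Of the bZIP factor genes, 5 of 27 had a peak (18.5%, odds ratio 10.9, Fisher's exact test, adjusted p = 0.00106): *cebp-1*, *jun-1*, *xbp-1* (signal 72.4), which acts in the unfolded protein response, *atf-2* (42.2) and *zip-2* (38.1). The *zip-2* peak ranked 213 in replicate 1 but 4117 in replicate 2. Genes of G protein-coupled chemoreceptors had one in 5 of 1283 (0.390%, odds ratio 0.176, Fisher's exact test, adjusted p = 4.14e-06), the strongest at *srz-62* (66.7, with an AP-1 site) and *srh-269* (52.7). Against genes matched on the GC content of their window, a setting chosen after seeing the data, the odds ratios fell to 6.40 for ribosomal protein genes, 9.34 for heat shock and 6.59 for bZIP genes and stayed past the threshold (Fisher's exact test, adjusted p = 1.18e-05, 0.0134 and 0.0254). Without replicate 2 the ribosomal odds ratio was 7.71 (Fisher's exact test, adjusted p = 4.66e-05), and over all 11 other settings it lay between 6.35, among genes with any pooled region in their window, and 20.9, with the narrower window.

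The other 17 lists did not pass the threshold. The JNK and p38 pathway list had 2 of 20 genes with a peak, *jun-1* and *vhp-1* (10%, Fisher's exact test, adjusted p = 0.189). It did pass when any annotated transcript start counted, with 3 genes (Fisher's exact test, adjusted p = 0.0422), and in the list without replicate 2 (Fisher's exact test, adjusted p = 0.0195). Body wall muscle had 3 of 30 (Fisher's exact test, adjusted p = 0.0820), with *act-2*, an actin gene (signal 77.4), and *unc-112*, the kindlin gene (48.8), both carrying AP-1 sites. This list passed with a window of 500 bp upstream to 200 bp downstream (Fisher's exact test, adjusted p = 0.0252) and with each peak given to its nearest gene only (Fisher's exact test, adjusted p = 0.0412), and had 1 gene without replicate 2. Histone genes had 4 of 50 (Fisher's exact test, adjusted p = 0.0819), led by *his-37* and *his-67* (47.7), and passed in both lists that left a replicate out (Fisher's exact test, adjusted p = 0.0153 and 0.00183) and with a window from 3000 bp upstream (Fisher's exact test, adjusted p = 0.0132), while against GC-matched genes the odds ratio was 1.23. Histone genes have near-identical copies, and how the authors' alignment treated reads that fit several of them is not given in the sources used here. Nuclear hormone receptors had 6 of 269, led by *nhr-50* (53.1) and *nhr-68* (49.4). Single genes with a peak came from spermatheca and actomyosin contraction (*rho-1*, 69.5, of 17), germline (*cgh-1*, 48.3, of 26), neurons (*mec-3*, 41.0, of 30), innate immunity and antimicrobial peptides (*zip-2*, of 28), and vulva, seam and larval timing (the Ras gene *let-60*, 36.4, of 27). Of these single genes, *cgh-1* and *zip-2* had their summit in the promoter. The summits counted for *rho-1*, *mec-3* and *let-60* lay farther upstream, at -1153, -1497 and -1396 bp from the 5' end. The first 2 of those were intergenic and the *let-60* one lay in another RNA gene. Some peaks of the lists without a call ranked low in 1 replicate. In replicate 1 *unc-112* ranked 1382 and *cgh-1* 1653, against 128 and 227 in replicate 2. The *let-60* peak ranked 300 in replicate 1 and 2519 in replicate 2. No gene with a peak was found among 15 of anchor cell invasion, 25 of basement membrane and matrix receptors, 18 of metal and oxidative stress, 18 of pharynx, 32 of intestine, 35 of epidermis and cuticle, 18 of insulin signalling and 156 collagens. With a window from 3000 bp upstream to 500 bp downstream, 1 of the 15 anchor cell invasion genes and 1 of the 156 collagens had a peak, without replicate 2 there were 2 of 18 insulin signalling genes and 1 collagen, without replicate 1 there was 1 collagen, and with windows to the gene's end 1 insulin signalling gene. None of these counts passed the threshold (Fisher's exact test, adjusted p from 0.127 to 0.824). The counts of 0 allow shares of up to 20.4% for anchor cell invasion and 2.40% for collagens (upper 95% Wilson bounds).

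**Figure D5:**
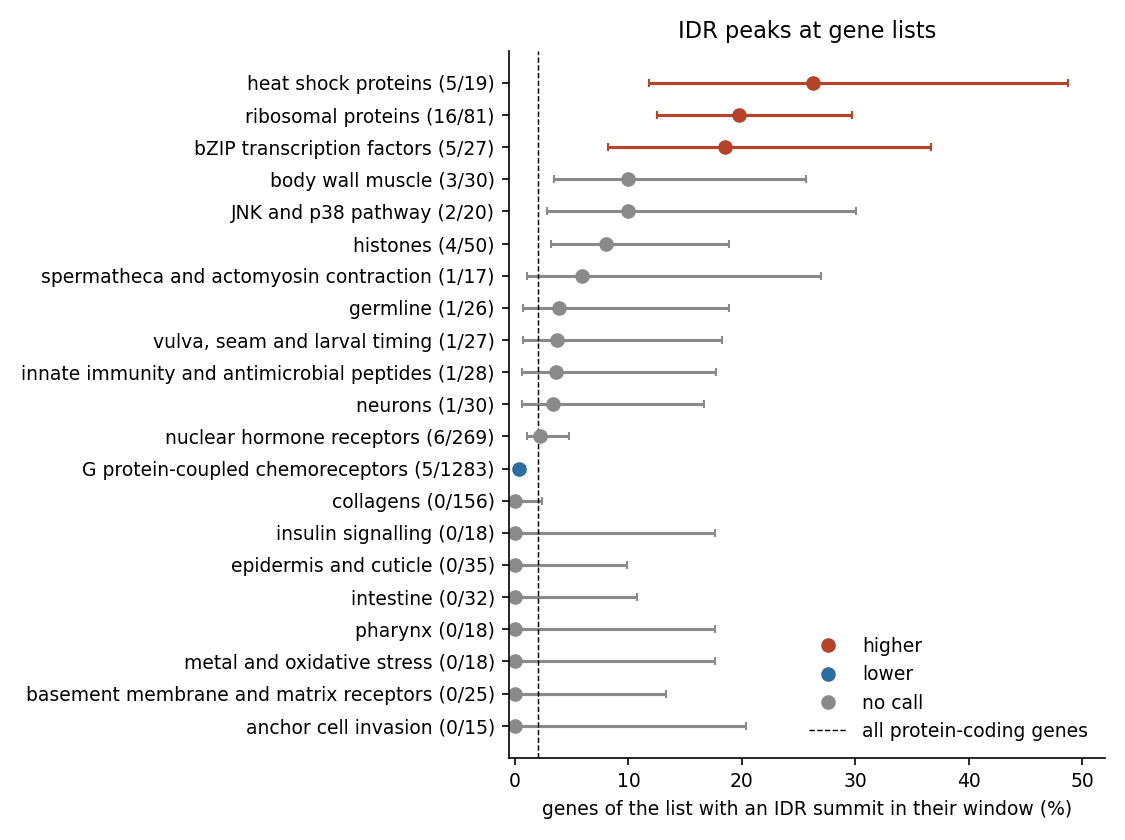
Share of each gene list with an IDR summit in the gene window (percent, with 95% Wilson intervals and the counts in brackets), lists above the rest of the genome in red, below in blue and without a call in grey, and the share over all protein-coding genes (2.06%) as a dashed line. Heat shock, ribosomal protein and bZIP genes stood at 18.5 to 26.3%.

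At the L3 stage FOS-1 is known from genetics to act in the anchor cell, which then crosses the basement membrane toward the vulval cells, and the genes tied to that role were looked up whatever their value. *egl-43* had a region in the pooled relaxed list at -442 bp from its 5' end, at rank 8901 with a signal of 15.1, and *zmp-1*, a matrix metalloprotease gene, had one at -980 bp, at rank 3139 with a signal of 20.5. Both ranks lie far below the IDR peaks. *cdh-3*, *him-4* and *fos-1* itself had no region in their windows. The peaks come from whole larvae, so low ranks or missing regions cannot show that FOS-1 leaves these genes unbound in the anchor cell. The *fos-1* gene (chromosome V 6003601 to 6016087) had 0 pooled regions within 20000 bp, against a median of 7 over all protein-coding genes, and 0.846% of genes had as few. Replicate 1 had 1 region there and replicate 2 had 2, against medians of 12 and 13. Control reads at the locus were not analysed here.

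Lists on the older ce10 build gave 537 IDR peaks and 17775 pooled regions, against 561 and 17769 on ce11. The ranked signals of their IDR peaks differed by at most 0.941%. Coordinates were not converted between the builds.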

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

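The GC matching with 1 region per peak, the GC-matched promoter share and 3 of the gene list alternatives were chosen after seeing the data. Of 175 recomputed values, 131 stayed the same, 27 lost their call, 2 gained one, 10 moved and 5 changed direction. A tested value stayed the same if it kept its direction and side of the threshold. A share or correlation did so within its error, and a count within a set ratio of the main count. The AP-1 odds ratio stayed past the threshold in all 9 alternatives (3.61 to 7.67), as did the promoter odds ratio in 7 (1.80 to 3.33) and the X share in 3 (1.48 to 1.62 times). Leaving out peaks within 20000 bp of *fos-1* removed none, so it tests nothing, although it is among the 131. Numbers of called gene lists stayed between 4 and 6 in 11 alternatives.

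Replicate agreement depended on the distance that counted as a match: 68.1% of the peaks matched in both replicates within 50 bp, 99.5% within 200 bp and 100% by intervals sharing 1 bp. It was 94.6% in the 280 strongest peaks and 41.2% when only the strongest 561 regions of each replicate were used. The rank correlation was 0.33 in the 280 strongest peaks. The number of higher 7-base sequences was 779 in the 280 strongest peaks, where fewer peaks were tested. It was 45 with GC-matched background and 3 with 1 matched region per peak, where the background was smaller as well. The difference in median signal with and without an AP-1 site lost its call in the 280 strongest peaks (1.84), within 50 bp (2.91) and without replicate 2. With either replicate left out it was 2.15 to 2.73, in the signal of a single replicate, whose scale is lower than the pooled one, so the sizes cannot be set beside each other. Within 50000 bp of *fos-1* there was 1 IDR peak. With GC-matched background the odds ratio turned to 0.929 for CAGCTG and 1.27 for the heat shock element, and with 1 matched region per peak to 1.05 for the heat shock element and 0.902 for the GC box. The DAF-16 element ranged from 0.688 to 1.17 over the left-out replicates. Beyond the GC matching itself, the cause of these changes was not tested. With 2 replicates of unstated depth, ranks below the strongest peaks have no error estimate.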

Other observations

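The tests of AP-1 regions below the IDR threshold, of the AP-1 share at ribosomal and chaperone genes, of the spacing around *fos-1* and *unc-119* and of extra copies of its locus were chosen only after the results were seen.

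AP-1 sites did not stop at the IDR threshold. They were found in 79 of the 1439 pooled regions at ranks 562 to 2000 (5.49%, 95% Wilson interval 4.43 to 6.79%), against 1.85% (1.65 to 2.07%) below rank 2000. Among the 2000 strongest pooled regions, 135 had a site, and genes with such a region from 1500 bp upstream to the gene's end included 5 of the 20 genes of the JNK and p38 pathway list against 0.596% of the other protein-coding genes (Fisher's exact test, adjusted p = 2.57e-06 over 21 lists). The 5 were *jun-1*, *vhp-1*, the kinase genes *dlk-1* (rank 1538, signal 25.6), *pmk-3* (rank 1039, signal 29.3, its summit at chromosome IV 8139191) and *max-2* (rank 1075, signal 28.9), the last 3 below the IDR threshold. In the narrower window at the 5' end, which is equally wide for all genes, the list had 3 of 20 (Fisher's exact test, adjusted p = 0.00207). Peaks with AP-1 sites at *jun-1*, *vhp-1*, *cebp-1*, *act-2* and *unc-112* had been seen before these tests were chosen. The p-values for the JNK and p38 pathway, bZIP and body wall muscle lists are therefore no independent support. The window to the gene's end is wider for longer genes, so gene length can raise its counts for any list, which was not tested. The 1865 regions without a site also marked the JNK and p38 pathway list in the wide window (7 of 20, Fisher's exact test, adjusted p = 0.00226) but not in the narrow one (4 of 20, Fisher's exact test, adjusted p = 0.0829). The difference between regions with and without a site was not tested. Regions without a site also marked intestine, insulin signalling and vulva, seam and larval timing in the wide window only (Fisher's exact test, adjusted p = 0.0280, 0.0280 and 0.00282). Body wall muscle genes with a region that had a site numbered 3 of 30 in either window (Fisher's exact test, adjusted p = 0.00357 in the narrow window and 0.00881 in the wide one). The bZIP list had 2 of 27 with a site in either window (Fisher's exact test, adjusted p = 0.0468 in the narrow window and 0.0849 in the wide one), and regions without a site marked 7 and 14 of its 27 genes (Fisher's exact test, adjusted p = 0.00327 and 2.25e-08).

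Of the 51 IDR peaks near small structural RNA genes, 1 had an AP-1 site, against 55 of the other 510 (Fisher's exact test, p = 0.0476, adjusted p = 0.524 over 11 groups).

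The AP-1 sites in IDR peaks were weighed against the peaks' GC content and promoter location. Matching the background on GC content left an odds ratio of 4.25 (95% interval 2.88 to 6.24), and leaving out all promoter summits left 4.70 (2.83 to 7.46), so neither accounts for the enrichment as a whole. A biological hypothesis that stays open is that a part of the peaks marks FOS-1 at AP-1 sites, possibly at *jun-1* and *cebp-1* among others. It was found and tested on the same lists, 505 of the 561 peaks had no whole site within 75 bp, and no comparison group tests it.

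Peaks at ribosomal protein and chaperone genes are the second pattern. Against genes matched on the GC content of their window, the ribosomal odds ratio fell from 12.1 to 6.40 (95% interval 3.08 to 12.8). GC content of the window thus does not account for the pattern as a whole, but it can account for a part. GC content around the summits was not matched for these genes. Of their 21 strongest peaks, 0% (upper bound 15.5%) lay within 200 bp of a small structural RNA gene, which argues against such genes as the cause. Another candidate explanation is that busy promoters are enriched in this assay without an AP-1 site: 0% of the 21 peaks had one, against 10.4% of the other 540, but with 21 peaks even a count of 0 could not pass the threshold (Fisher's exact test, p = 0.253), so this test decides nothing. Among the 2000 strongest pooled regions, those without a site marked 35 of 81 ribosomal and 8 of 19 heat shock genes at the 5' end (Fisher's exact test, adjusted p = 9.98e-21 and 3.24e-05) and those with a site 0 of either, where 0.457% and 0.456% of the other genes had one. At shares that low a count of 0 is likely for lists of this size, so the contrast decides nothing. Enrichment that does not need FOS-1 cannot be told apart from FOS-1 binding without its site, since the control was not analysed, and no comparison group tests a biological explanation.

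The third pattern is the stretch without regions around *fos-1*, from chromosome V 5976480 to 6031237, which was free of summits in the pooled list and in both replicates. Stretches as wide held the midpoints of 0.531% of protein-coding genes in replicate 1, 0.491% in replicate 2 and 0.451% (90 of 19973) in all 3 lists, which argues against chance spacing at this gene, although the lists are not independent because the pooled one uses the reads of both replicates. Of the 36-base sequences of the stretch 0.729% occur more than once in the genome, below the median of 5.34% over 9996 equally wide stretches, which argues against repeated sequence. The strain carries *fos-1* in an integrated transgene, and extra copies of the locus could raise the control there and hide peaks: in both replicates the stretch reached 15.15 kb or more beyond each end of the gene, while *unc-119*, the gene mutated in this strain and looked up beside it, had summits inside the gene in all 3 lists, with gaps at its midpoint of 15.4 kb in the pooled list and 1.26 and 2.63 kb in the replicates. Whether the transgene carries *unc-119* sequence of this species is not given in the sources used here. The control was not analysed, so extra copies stay open as an explanation. A lack of FOS-1 binding stays open as well. Within 20000 bp, 80.3% of protein-coding genes had no IDR peak but only 0.846% had no pooled region. Most genes without a peak thus still had weak regions near them. Whether such weak regions need FOS-1 was not tested, so these shares do not decide whether a lack of binding is the sole account.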
